A study of Mus musculus with 16 samples.

How the data were processed

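RNA sequencing was performed on mouse CD4 T cells that had been driven toward the Th17 fate in culture. Per the labels' protocols, naive CD4 T cells were sorted magnetically from spleen and lymph nodes of mice with loxP-flanked PDH alleles, either without Cre (wild type, WT) or with CD4-Cre (knockout, KO). The sample titles write PHD, which is also a name of the HIF prolyl hydroxylases, where the protocols, the series title and its design text write PDH or pyruvate dehydrogenase. The latter was used here. The cells were cultured for 3 days on plate-bound anti-CD3 at 5 µg/mL with anti-CD28 at 1 µg/mL, IL-6 at 30 ng/mL, TGFβ at 2 ng/mL and an antibody blocking IFNγ at 5 µg/mL. For acetate treatment, sodium acetate was present at 10 mM throughout the differentiation. RNA was prepared with a NucleoSpin kit and libraries with the TruSeq Stranded mRNA kit, per the labels' protocols. The 16 libraries formed 4 groups of 4, named WT untreated, KO untreated, WT acetate and KO acetate. By the labels no group was a control for sodium or for CD4-Cre alone. Effects of sodium and of Cre were therefore not separated from those of acetate and of the knockout. The labels do not say which libraries came from separate animals or cultures, so p-values measure the spread between these libraries only, which may be technical.

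The authors deposited estimated counts per gene as whole numbers for the 16 libraries in 1 table. The submitters' processing notes name Salmon, DESeq2 and DESeq without versions. The genome build, the annotation and the step that rounded the estimates are not given in the sources used here. The table held 15571 genes by Ensembl identifier, and every gene reached at least 10 counts in at least 3 libraries, so genes below that level were not analysed here. Library totals lay between 24.57 and 33.72 M counts and differed between libraries, and the values were used as estimated counts without further rounding. Gene names were taken from a reference table of identifiers, in which 15221 identifiers matched and 350 did not; 15 names were shared by more than 1 identifier. No coordinates were used. Genes that share reads with near-identical copies, such as ribosomal protein genes and mitochondrial genes with nuclear copies, are uncertain, because the estimates divide such reads between copies.

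Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), using TMM scaling, filterByExpr on the groups, and the robust quasi-likelihood F test with Benjamini-Hochberg adjustment over the 14985 genes tested. One fit held all 16 libraries, so that the 4 groups shared 1 estimate of the spread, with no replicate term. A gene was called when its adjusted p was under 0.05. The words rose, fell, higher and lower are used of genes for calls made in this way. All gene-level adjusted p-values in the text are from this edgeR test unless another tool is named. Abundance is given as CPM, a gene's count scaled to the effective (TMM-scaled) library size, mean ± SD over the 4 libraries of a group. Log2 fold changes are given with their standard error (SE). The comparisons were KO against WT without and with acetate, acetate against untreated in each genotype, KO acetate against WT untreated, and the interaction, which is the acetate effect in KO cells minus that in WT cells. The common biological coefficient of variation was 0.144. Replicate libraries differed by more than sampling noise in all 24 pairs within groups (chi-square per degree of freedom 6.45 to 228.9), so none was treated as a duplicate.

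The groups of genes described were 32 lists fixed before the data were examined, of which 30 had at least 5 tested members. Each was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The camera test with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. Members that rose or fell were counted after adjustment over all genes and after adjustment over the list alone. The genes named were also chosen by a rule set before the data were examined. For each comparison these were Pdha1, Pdhb, Dlat, Pdhx and Dld; the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups (for the interaction, without the last condition); up to 4 members of each list with the smallest adjusted p; and Il17a, Il17f, Il21, Il22 and Il23r. Predicted genes, unnamed identifiers, immunoglobulin and T cell receptor segments and sex-linked genes were left out of the rule, and only part of the genes it admits are named. Some others are not reported here.

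Correlations of fold changes across genes were computed for pairs of comparisons. For pairs that share libraries, values from simulated unchanged groups and from dividing the shared libraries 2 and 2 between the comparisons were computed as well. The edgeR steps were tested on simulated counts with 200 genes changed in 1 group, made from the real means and library sizes. The changed genes were drawn from those with a mean count of at least 50, so recovery at lower counts was not measured. In the KO untreated against WT untreated comparison, 73.1% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, with 3 false calls among 14731 genes. For KO acetate against KO untreated the shares were 73.1%, 89.6% and 97.0%, with 11 false calls. For the interaction they were 49.3%, 80.6% and 92.4%, with 10 false calls. The simulated libraries were drawn independently, with as many rises as falls and far fewer changed genes than most real comparisons called. These rates therefore need not hold for the real comparisons. The alternatives tried were DESeq2 size factors, no scaling beyond the library total, no filter on low counts, a mean count of at least 50, DESeq2 1.42.0, the replicate number as a block, a fit of only the groups compared, and leaving out each replicate. Chosen after seeing the data were fits without the 4 libraries in which a single gene with no name in the reference took over 3% of counts, with that gene's log2 share as a covariate, and with a term for replicates 1 and 2 against 3 and 4.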

Results

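Th17 cells, the IL-17-producing class of helper T cells, were profiled by RNA sequencing in a design that crossed a T cell knockout of PDH, the enzyme complex that turns pyruvate into acetyl-CoA in mitochondria, with sodium acetate. Cells can turn acetate into acetyl-CoA by another route. There were 4 libraries in each of the groups WT untreated, KO untreated, WT acetate and KO acetate. Total estimated counts averaged 31.59 ± 2.24 M counts (SD, n = 4) in WT untreated, 29.21 ± 1.68 M in KO untreated, 30.35 ± 4.35 M in WT acetate and 27.49 ± 0.722 M in KO acetate libraries. The first principal component of log2 CPM held 31.3% of the variance of the 16 libraries. It placed the KO untreated libraries between −55.70 and −50.03, the WT untreated libraries between −14.18 and 1.76, and the acetate libraries of both genotypes between 20.88 and 34.50. The second component, with 16.2% of the variance, placed KO acetate libraries between −42.76 and −14.02 and WT acetate libraries between −2.88 and 30.20. One gene with no name in the reference took 0.267% to 9.14% of a library's counts and exceeded 3% in WT untreated 1 (5.89%), KO untreated 1 (9.14%), KO untreated 2 (3.27%) and KO acetate 2 (8.0%), called the high-share libraries here.

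**Figure D1:**
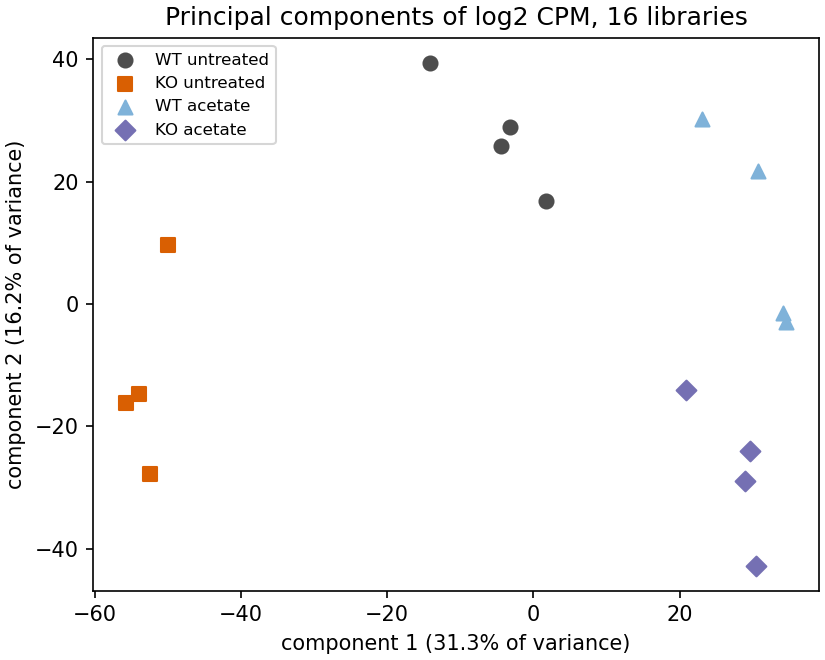
Positions of the 16 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, with the share of variance each component held. Each point is 1 library, with shape and colour for its group. The 4 KO untreated libraries lay at −50.03 or below on the first component, and the 8 acetate libraries at 20.88 or above.

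The subunit genes of the PDH complex were measured in every group, to see whether the knockout showed in these counts. Pdha1, which encodes the E1 alpha subunit, stood at 247 ± 12.6 CPM in WT untreated, 225 ± 11.5 CPM in KO untreated, 259 ± 10.8 CPM in WT acetate and 248 ± 13.0 CPM in KO acetate libraries (SD, n = 4). Its change between KO and WT untreated cells was −0.14 (log2, SE 0.058, adjusted p = 0.0761). It fell by 0.20 with an adjusted p of 0.0482 in edgeR without scaling, by 0.14 with 0.0304 in DESeq2 and by 0.22 with 0.0455 in edgeR without the 4 libraries with over 3% of counts on the unnamed gene. The E1 beta subunit gene Pdhb was at 96.6, 102, 87.7 and 86.7 CPM in the same order. Dlat (E2) was at 75.9, 66.6, 87.3 and 84.3 CPM, and Dld (E3) at 121, 127, 125 and 136 CPM. Pdhx, the E3-binding protein gene, was at 23.7 ± 0.933 CPM in WT untreated and 18.9 ± 1.15 CPM in KO untreated cells, with a log2 fold change of −0.32 (adjusted p = 0.00256). The value was −0.26 without those 4 libraries, with fewer libraries and an adjusted p of 0.0879. The protocols name PDH, and the sample titles PHD, without saying which gene or which part of it was deleted. A count over a whole gene cannot show the loss of a few exons, so these levels do not check the genotype labels.

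The comparison of KO with WT cells without acetate asked how Th17 cells of the 2 genotypes differed. In KO cells 19 of 26 genes of the ATF4 response, which cells switch on when amino acids run short or mitochondria are stressed, rose, as did 8 of 15 genes of serine and one-carbon metabolism and 13 of 21 interferon-stimulated genes. Of 22 glycolysis genes 15 fell, and of 18 hypoxia genes 8 fell and 1 rose. These list calls by camera at a preset correlation were all lost with an estimated correlation, at an adjusted p between 0.0782 and 0.689. Fry, which asks only whether a list's genes move one way on balance, called each of these lists (adjusted p = 3.18e-06 to 0.00492). Il17a, the signature cytokine gene of these cells, was at 135 ± 44.4 CPM in WT and 138 ± 27.7 CPM in KO cells (SD, n = 4). Il23r, the receptor gene through which IL-23 sustains Th17 cells, fell from 27.3 ± 3.13 to 7.82 ± 2.48 CPM. Il22 fell from 19.6 ± 4.56 to 5.98 ± 2.93 CPM, and Il21 rose from 279 ± 14.4 to 477 ± 55.6 CPM. Altogether 5481 of 14985 genes were called, 2699 higher and 2782 lower in KO cells, of which 685 rose and 245 fell more than 2-fold.

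Among the 26 tested members of the ATF4 and integrated stress list, 19 rose and none fell, whether adjusted over all genes or adjusted over the list alone (camera adjusted p = 6.06e-13, and adjusted p = 0.299 with an estimated correlation). Atf4 itself rose from 292 ± 8.31 to 570 ± 35.5 CPM, and its relative Atf5 from 14.9 ± 0.925 to 50.9 ± 5.63 CPM (log2 fold change 1.78, SE 0.113, edgeR adjusted p = 1.3e-08). Trib3, a pseudokinase induced by ATF4, rose 7.54-fold, the stress regulator Nupr1 7.34-fold, Stc2 6.21-fold and the cationic amino acid carrier Slc7a3 7.83-fold, and the neutral amino acid carrier Slc7a5 rose 2.09-fold. Of 15 genes in the serine and one-carbon list, 8 rose and none fell by either adjustment (camera adjusted p = 0.00103, and adjusted p = 0.0782 with an estimated correlation). These included Shmt2, the mitochondrial serine hydroxymethyltransferase (247 ± 18.2 to 509 ± 45.7 CPM), and Phgdh, the first enzyme of serine synthesis (285 ± 6.62 to 430 ± 39.7 CPM).

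Of 22 glycolysis genes, 15 fell and none rose, or 16 when adjusted over the list alone (camera adjusted p = 6.05e-09, and adjusted p = 0.117 with an estimated correlation). The lactate exporter Slc16a3 fell from 119 ± 9.54 to 30.2 ± 2.90 CPM (log2 fold change −1.98, SE 0.134, edgeR adjusted p = 5.92e-08). Hexokinase 1 (Hk1) fell from 230 ± 11.4 to 147 ± 5.38 CPM, aldolase (Aldoa) from 1096 ± 103 to 699.7 ± 54.6 CPM, and Pfkfb3, a regulator of phosphofructokinase, from 54.9 ± 2.10 to 36.1 ± 1.95 CPM. In the hypoxia and HIF1 list 8 of 18 genes fell and 1 rose by either adjustment (camera adjusted p = 0.00533, and adjusted p = 0.689 with an estimated correlation). Hif1a, the oxygen-regulated transcription factor, fell from 660.2 ± 89.9 to 324 ± 31.1 CPM, the mitophagy gene Bnip3 2.68-fold and the prolyl hydroxylase subunit gene P4ha1 1.47-fold. The cell cycle list had 8 of 26 genes lower and none higher by either adjustment, with Ccnb2 1.49-fold and Plk1 1.37-fold lower (camera adjusted p = 0.00926, adjusted p = 0.759 with an estimated correlation, and 0.163 at the preset correlation with 5 genes lower without the high-share libraries).

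Of 21 interferon-stimulated genes 13 rose and none fell, or 14 when adjusted over the list alone (camera adjusted p = 1.88e-05, and adjusted p = 0.0782 with an estimated correlation). Isg15, Ifit1 and Irf7 rose 8.02-fold, 7.17-fold and 5.15-fold from levels below 0.5 CPM. Without scaling, 12 genes of this list rose and 1 fell. The list's median log2 fold change was 0.52, and 0.48 without the 4 libraries with over 3% of counts on the unnamed gene.

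Among genes of T cell function, the transcription factor Stat3, which relays IL-6 and IL-23 signals, fell from 376 ± 25.1 to 244 ± 15.6 CPM, and the inhibitory receptor gene Ctla4 fell 2.19-fold. The early activation genes Nr4a1 and Tnfrsf9 fell 2.01-fold and 2.21-fold, while Il2 rose from 282 ± 55.9 to 556 ± 69.2 CPM and Myc 1.49-fold. The Th17 list as a whole had 7 genes higher and 6 lower of 23 by either adjustment (camera adjusted p = 0.852). Il17a (log2 fold change 0.02, SE 0.294, adjusted p = 0.962) and Il17f (−0.27, SE 0.222, adjusted p = 0.372) did not pass the edgeR test. The largest changes outside the lists were rises of the water channel Aqp4 (0.272 ± 0.0927 to 5.70 ± 2.28 CPM) and the actin-bundling gene Fscn1 (0.786 ± 0.0326 to 10.4 ± 3.09 CPM), and falls of Ramp3, Tg, Dusp3 and Vat1 by 12.7-, 5.12-, 3.70- and 3.50-fold.

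Every gene named here that the reported fit called higher or lower had all 4 libraries of one group above all 4 of the other. With library totals as the only scaling, 1914 genes were higher and 3217 lower, against 2699 and 2782 with TMM, and without the 4 libraries with over 3% of counts on the unnamed gene 3361 genes were called, 3185 of them among the 5481. Dlat (log2 fold change −0.19, adjusted p = 0.0326) lost its call when any of WT untreated 2 or 4 or KO untreated 1, 3 or 4 was left out, with values between −0.21 and −0.16.

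**Figure D2:**
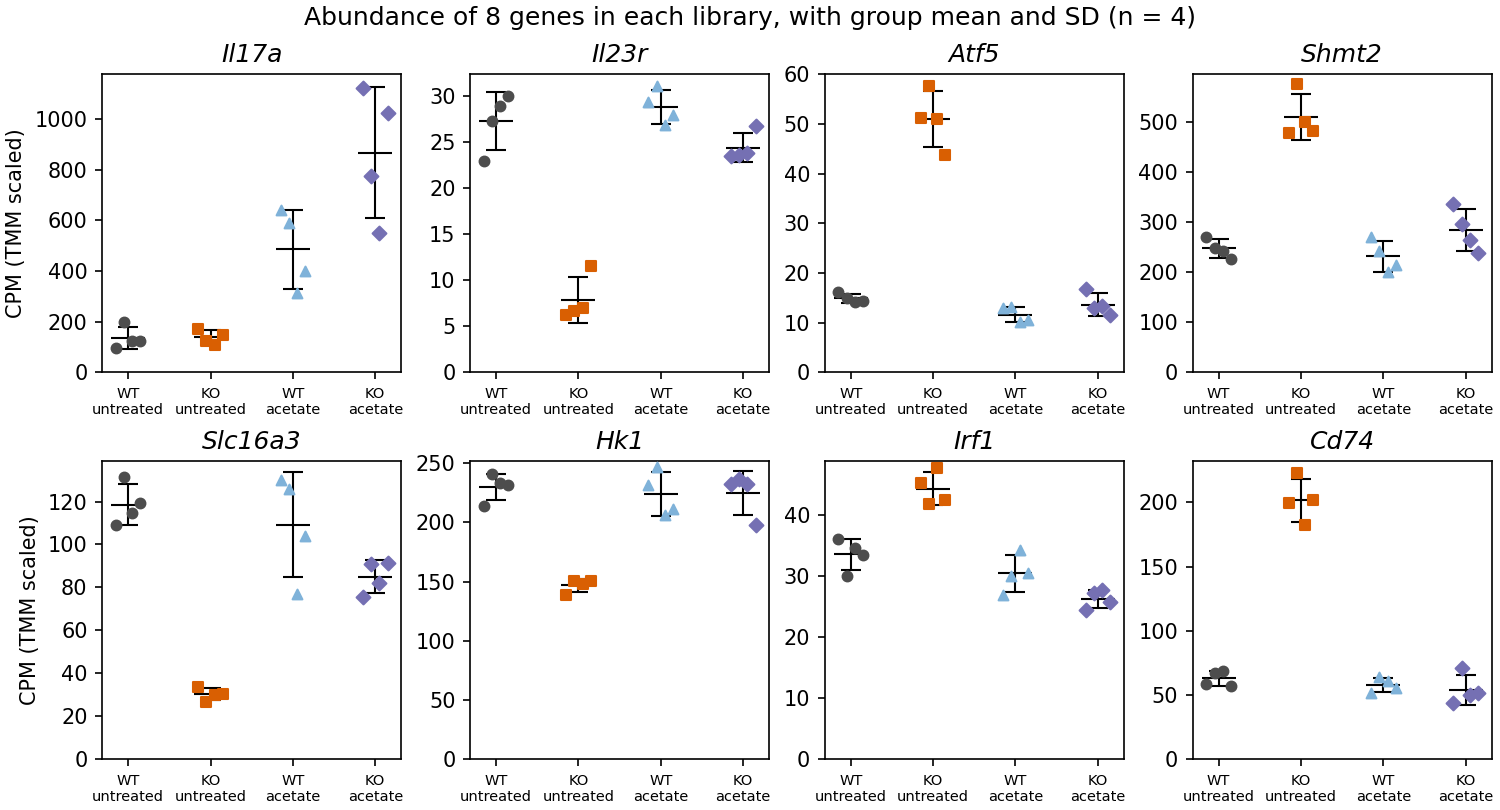
TMM-scaled CPM (vertical axes, from 0) of 8 genes in each of the 16 libraries, by group. Points are libraries and lines give the group mean and SD (n = 4). Atf5, Shmt2, Irf1 and Cd74 stood highest and Il23r, Slc16a3 and Hk1 lowest in KO untreated libraries, and Il17a stood higher in both acetate groups (485 and 868 CPM) than in both untreated groups (135 and 138 CPM).

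The comparison of KO acetate with KO untreated cells asked what changed with acetate in KO cells. Il17a rose with acetate in KO cells, from 138 ± 27.7 to 868 ± 258 CPM (log2 fold change 2.66, SE 0.310, edgeR adjusted p = 1.71e-05). Il17f rose from 419 ± 88.7 to 1117 ± 254 CPM, Il22 from 5.98 ± 2.93 to 16.7 ± 2.97 CPM and Il23r from 7.82 ± 2.48 to 24.4 ± 1.54 CPM. Il21 fell from 477 ± 55.6 to 302 ± 49.9 CPM. With acetate 14 of 21 interferon-stimulated, 14 of 26 ATF4, 6 of 15 serine and one-carbon, 15 of 25 cholesterol synthesis and 11 of 18 p53 genes fell in KO cells, and 9 of 20 T cell activation and 8 of 13 Th1 genes rose. Of these list calls only that of the interferon-stimulated genes held with an estimated correlation, the others having an adjusted p between 0.412 and 0.609. Fry called each of these lists (adjusted p = 1.5e-07 to 0.00873). In all 6550 genes were called, 3314 higher and 3236 lower with acetate, of which 852 rose and 651 fell more than 2-fold.

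Of the 23 Th17 genes 10 rose and 2 fell by either adjustment (camera adjusted p = 0.00892, and adjusted p = 0.486 with an estimated correlation). In the T cell activation list 9 of 20 genes rose and 2 fell, or 10 and 2 when adjusted over the list alone (camera adjusted p = 0.00795, and adjusted p = 0.486 with an estimated correlation), among them Nr4a1 (2.38-fold) and Tnfrsf9 (2.64-fold). The Th1 list had 8 genes higher and 3 lower of 13 by either adjustment (camera adjusted p = 0.0329, and adjusted p = 0.412 with an estimated correlation). Its rises included Stat4, the transcription factor downstream of IL-12 (42.1 ± 9.60 to 161 ± 23.0 CPM), granzyme B (Gzmb, 2.93-fold) and Fas ligand (Fasl, 2.95-fold). Of 6 tested markers of CD8 and cytotoxic cells, 4 rose by either adjustment (camera adjusted p = 0.0221, and adjusted p = 0.409 with an estimated correlation), including perforin (Prf1, 1.64 ± 0.509 to 6.77 ± 1.57 CPM) and Cd8b1 (6.20 ± 1.23 to 12.9 ± 1.98 CPM). Ctla4 rose 3.51-fold, and Cxcr5, the chemokine receptor of follicular helper cells, rose 6.12-fold.

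Of the 21 interferon-stimulated genes 14 fell and 1 rose with acetate in KO cells, or 15 and 1 when adjusted over the list alone. This call held with an estimated correlation (camera adjusted p = 1.83e-05, and adjusted p = 0.0476 with an estimated correlation). The GTPase gene Gbp2 fell from 317 ± 57.1 to 86.7 ± 12.3 CPM and Irf1 from 44.3 ± 2.72 to 26.2 ± 1.45 CPM. In the ATF4 list 14 of 26 genes fell and 1 rose by either adjustment (camera adjusted p = 0.000107, and adjusted p = 0.588 with an estimated correlation), with Atf5 3.74-fold and Slc7a5 1.98-fold lower. Serine and one-carbon genes numbered 15, of which 6 fell and none rose by either adjustment, Shmt2 1.80-fold (camera adjusted p = 0.0482, and adjusted p = 0.412 with an estimated correlation). Without scaling 4 of them fell and 1 rose, and the camera adjusted p was 0.0939 without the high-share libraries. The p53 and apoptosis list had 11 of 18 genes lower and none higher, or 12 adjusted over the list alone, and 7 lower and 1 higher without scaling (camera adjusted p = 0.00608, and adjusted p = 0.587 with an estimated correlation). Its falls included the death gene Bbc3 (38.1 ± 3.66 to 20.2 ± 3.09 CPM) and Ccng1 (1.47-fold).

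Cholesterol synthesis genes fell in 15 of 25 cases and rose in 2 by either adjustment, but without scaling 6 fell and 2 rose (camera adjusted p = 0.00795, and adjusted p = 0.609 with an estimated correlation). Idi1 fell from 843 ± 41.0 to 508 ± 16.8 CPM. Of 26 cell cycle genes 14 fell and 1 rose by either adjustment, against 4 and 2 without scaling (camera adjusted p = 0.0185, and adjusted p = 0.609 with an estimated correlation). Among them Cdc20, an activator of mitotic exit, fell 1.62-fold. Slc16a3 rose from 30.2 ± 2.90 to 85.0 ± 7.65 CPM. The largest changes outside the lists included rises of Ramp3, Ccn4, Upp1, Vat1 and Tg, between 9.19-fold for Tg and 23.5-fold for Ramp3. Falls included those of Kynu, an enzyme of tryptophan breakdown (10.4 ± 1.97 to 0.460 ± 0.292 CPM), Aqp4, Dagla, Myh11, the cytokine gene Il9 (29.3 ± 13.8 to 2.61 ± 1.48 CPM) and the prolactin receptor Prlr.

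Dlat rose 1.27-fold and Pdhb fell 1.17-fold (edgeR adjusted p = 4e-04 and 0.00115, n = 4 per group), Pdhb losing its call without scaling (adjusted p = 0.18). Pdhx (log2 fold change 0.21, adjusted p = 0.0343, libraries overlapping) lost its call without KO untreated 1, 2 or 4 or KO acetate 1, 2 or 4 (0.15 to 0.26). Pdha1 (0.14, SE 0.058, adjusted p = 0.0571) passed without KO acetate 4 (0.17), without scaling (0.25), in DESeq2 (0.14) and with a term for replicates 1 and 2 against 3 and 4 (0.14). Without scaling the median log2 fold change of all genes was 0.10, against −0.01 with TMM, and 4229 genes were higher and 2085 lower. Every other gene named as higher or lower had no overlap between the 4 libraries of each group.

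In WT cells the comparison with and without acetate asked what changed with acetate in cells without the knockout. Il17a rose from 135 ± 44.4 to 485 ± 154 CPM (log2 fold change 1.84, SE 0.302, edgeR adjusted p = 0.00146) and Il17f from 505 ± 109 to 952 ± 234 CPM. Il23r (27.3 and 28.8 CPM), Il22 (19.6 and 24.3 CPM) and Il21 (279 and 229 CPM) did not pass the test. Ifng, whose protein the culture antibody blocks, rose from 0.656 ± 0.140 to 3.04 ± 0.972 CPM and the Th1 transcription factor Tbx21 from 22.6 ± 3.67 to 45.5 ± 10.1 CPM. Of the fixed lists, 11 of 25 cholesterol synthesis, 7 of 22 glycolysis, 9 of 26 cell cycle and 7 of 18 p53 genes fell, and 9 of 20 T cell activation, 5 of 13 Th1 and 3 of 8 Tfh genes rose. With an estimated correlation camera called none of the lists, and these had an adjusted p between 0.286 and 0.419. Fry called each of these lists (adjusted p = 0.00218 to 0.0142). In all 2315 genes were called, 1183 higher and 1132 lower, of which 349 rose and 101 fell more than 2-fold.

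Of 25 cholesterol synthesis genes 11 fell and none rose, or 14 adjusted over the list alone and 6 without scaling (camera adjusted p = 7.8e-09, and adjusted p = 0.342 with an estimated correlation). Idi1 stood at 578 ± 62.2 and 431 ± 32.8 CPM without and with acetate, and Sc5d at 112 ± 3.41 and 86.6 ± 2.30 CPM. In the fatty acid synthesis list 4 of 15 fell and none rose, or 5 fell and 1 rose adjusted over the list alone, and 2 fell without scaling or without the high-share libraries (camera adjusted p = 0.0316, and adjusted p = 0.419 with an estimated correlation). Fasn, the fatty acid synthase gene, fell from 484 ± 50.5 to 344 ± 43.4 CPM. Glycolysis genes fell in 7 of 22 cases with none higher, or 9 adjusted over the list alone and 4 without scaling (camera adjusted p = 0.000917, and adjusted p = 0.393 with an estimated correlation). They included Pfkl (194 ± 15 to 117 ± 5.49 CPM) and Tpi1 (1.38-fold). The cell cycle list had 9 of 26 genes lower and none higher, or 12 adjusted over the list alone, 3 without scaling and 5 without the high-share libraries (camera adjusted p = 2.69e-05, and adjusted p = 0.419 with an estimated correlation). Here Cdc20 fell 1.45-fold. The p53 and apoptosis list had 7 of 18 genes lower and none higher, or 8 adjusted over the list alone (camera adjusted p = 0.000817, and adjusted p = 0.409 with an estimated correlation), with Ccng1 1.36-fold lower.

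The T cell activation list had 9 genes higher and 1 lower of 20 by either adjustment, and 5 higher without the high-share libraries (camera adjusted p = 0.00108, and adjusted p = 0.339 with an estimated correlation). Il2 went from 282 ± 55.9 to 598 ± 35.4 CPM. Of 13 Th1 genes 5 rose and none fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0031, and adjusted p = 0.286 with an estimated correlation). The Tfh list had 3 higher and 1 lower of 8, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00153, and adjusted p = 0.286 with an estimated correlation). Cxcr5 was 2.96-fold and Bcl6, the master regulator of follicular helper cells, 1.77-fold higher. For the Th17 list 3 of 23 rose and 2 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.0316, and adjusted p = 0.42 with an estimated correlation). Its camera adjusted p was 0.0926 without the high-share libraries, and none of it fell without scaling. Of 6 CD8 and cytotoxic markers 2 rose by either adjustment (camera adjusted p = 0.0464, and adjusted p = 0.339 with an estimated correlation), with Prf1 2.57-fold higher. Of 25 histone acetylation enzymes 1 rose and 4 fell, or 2 and 6 adjusted over the list alone, and the deacetylase gene Sirt1 fell 1.40-fold (camera adjusted p = 0.0464, adjusted p = 0.339 with an estimated correlation, and 0.054 at the preset correlation without the high-share libraries). The interferon-stimulated list had 2 genes higher and 3 lower by either adjustment and a median log2 fold change of 0.01 (camera adjusted p = 0.482), with Gbp2 2.28-fold lower.

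The largest rises outside the lists were of Prrt1 (0.686 ± 0.290 to 6.90 ± 0.377 CPM), Ccn4, Rcn3, Pde4a, the cytokine gene Il3 and Rcor2, between 4.13-fold for Rcor2 and 10.0-fold for Prrt1. The largest falls were of Myh11 (7.22 ± 3.32 to 0.679 ± 0.309 CPM), Ckmt1, Gap43, Robo3 and Tmem176a. Without scaling 1196 genes were higher and 558 lower. The Il17f call (adjusted p = 0.0139) ended without the 4 libraries with over 3% of counts on the unnamed gene (log2 fold change 0.92 with SE 0.224 before, 0.81 after, adjusted p = 0.0822). Dlat (0.20, adjusted p = 0.0454) lost its call without WT untreated 1, 3 or 4 or WT acetate 1 or 2 (0.15 to 0.24).

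The comparison of KO with WT cells in the presence of acetate asked how the genotypes differed when both had acetate. A difference here need not be a remainder of the one without acetate. Areg, which encodes an epidermal growth factor family ligand, was at 5.62 ± 0.862 CPM in KO and 2.38 ± 0.307 CPM in WT cells. The transcription factor Sox4 was at 37.9 ± 1.72 and 21.7 ± 3.13 CPM, the kinase gene Dclk1 at 79.5 ± 14.2 and 31.3 ± 6.61 CPM, and B3galt2 at 8.80 ± 1.06 and 3.46 ± 0.681 CPM. Without acetate the Areg libraries of the genotypes overlapped (4.70 to 6.09 CPM in WT, 4.95 to 7.31 CPM in KO). So did those of Dclk1 (11.93 to 20.15 and 14.11 to 17.68 CPM), while those of Sox4 did not (7.63 to 8.60 and 10.47 to 12.86 CPM). Acetate changed Areg by −1.15 (log2) in WT and −0.05 in KO cells, and Dclk1 by 0.88 and 2.27. Pycard, the inflammasome adaptor gene, was lower in KO cells, at 23.8 ± 2.59 against 34.8 ± 2.93 CPM. The edgeR test called 150 genes, 73 higher and 77 lower, of which 20 rose and 2 fell more than 2-fold. Of the 150, 105 were also called in the same direction between KO and WT untreated cells, and 1 in the opposite direction.

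Areg and B3galt2 had an edgeR adjusted p of 0.00119, Sox4 of 0.000469, Dclk1 of 0.00346 and Pycard of 0.00896, and each kept its call when any single library was left out (n = 4 per group), though Pycard had 0.0526 in a fit of only these 8 libraries. Csf2, which encodes GM-CSF, was at 43.1 ± 6.79 CPM in KO and 14.2 ± 5.55 CPM in WT cells (log2 fold change 1.60, adjusted p = 0.0297), but its call ended without WT acetate 2, 3 or 4 or KO acetate 1 or 3 (1.39 to 1.81). Also dependent on single libraries were the calls of the stress gene Sesn2 (0.58, ended without WT acetate 1, 3 or 4 or KO acetate 1, 0.48 to 0.67) and of the complex I gene Ndufv2 (−0.32, ended without any WT acetate library or KO acetate 1 or 3, −0.38 to −0.26). The cyclin gene Ccnb1 was another (−0.32, ended without WT acetate 3 or 4 or KO acetate 1 or 3, −0.35 to −0.31). Il17a was at 868 ± 258 CPM in KO and 485 ± 154 CPM in WT cells, which did not pass the test (0.84, SE 0.293, adjusted p = 0.154). Nor did Il17f, Il22 or Il23r. Il21 (0.40, SE 0.120, adjusted p = 0.0974) passed without KO acetate 2 (0.49), without the high-share libraries (0.49) and in DESeq2 (0.395). It also passed with the replicate number as a block (0.40, edgeR adjusted p = 0.036).

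The preset camera test called 12 of 30 lists here, and neither camera with an estimated correlation nor fry called any. The Th17 list had 1 of 23 genes higher, or 4 adjusted over the list alone and 5 without the high-share libraries (camera adjusted p = 0.00208, and adjusted p = 0.399 with an estimated correlation). Of 40 nuclear OXPHOS genes 1 fell, or 15 adjusted over the list alone and 7 without the high-share libraries (camera adjusted p = 2.78e-10, and adjusted p = 0.399 with an estimated correlation). Of 26 cell cycle genes 2 fell, or 10 adjusted over the list alone, 5 without the high-share libraries and none without scaling (camera adjusted p = 3.58e-09, and adjusted p = 0.399 with an estimated correlation). One of 26 ATF4 genes rose by either adjustment (camera adjusted p = 3.17e-06, and adjusted p = 0.521 with an estimated correlation). The other 8 lists were called lower for naive and memory T cells, glycolysis, the TCA cycle, fatty acid oxidation, mitochondrially encoded genes and NRF2 and glutathione, and higher for fatty acid and cholesterol synthesis, with at most 1 gene called in each (camera adjusted p = 0.00208 to 0.0468). With an estimated correlation they had an adjusted p between 0.399 and 0.816. The calls of mitochondrially encoded, NRF2 and glutathione and cholesterol synthesis genes ended without the high-share libraries (camera adjusted p = 0.104, 0.081 and 0.161). Without scaling 28 genes were higher and 50 lower. The count of 150 was 16 in a fit of only these groups, 74 with the unnamed gene's share as a covariate, 234 with a term for replicates 1 and 2 against 3 and 4, 535 without the high-share libraries and 826 in DESeq2. It went to 59, 21 and 42 without WT acetate 2, 3 and 4, to 22 and 24 without KO acetate 1 and 3, and to 661 and 371 without KO acetate 2 and 4.

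The comparison of KO acetate with WT untreated cells asked how far the treated knockout cells stood from untreated WT cells. It joins the effects of the knockout and of acetate. In the treated KO cells 24 of 26 cell cycle and 12 of 22 glycolysis genes were lower, and 8 of 23 Th17 genes were higher. Each of these 3 list calls was lost with an estimated correlation, at an adjusted p of 0.171. Fry called each of these lists (adjusted p = 0.000342 to 0.000417). Il17a was 6.42-fold (868 ± 258 against 135 ± 44.4 CPM) and Il17f 2.21-fold higher, Csf2 stood at 43.1 ± 6.79 against 7.11 ± 2.03 CPM, and Il23a, a subunit gene of IL-23, at 6.69 ± 3.47 against 0.725 ± 0.359 CPM. In all 3954 genes were called, 1935 higher and 2019 lower, of which 632 rose and 128 fell more than 2-fold. Of the 3954, 1734 were also called in the same direction for acetate in WT cells, and 0 in the opposite direction. Both comparisons use the WT untreated libraries, which adds to such sharing.

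Of 26 cell cycle genes 24 were lower and none higher, or 25 adjusted over the list alone and 18 without scaling, with Cdc20 1.80-fold and Ccnb2 1.58-fold lower (camera adjusted p = 1.03e-13, and adjusted p = 0.171 with an estimated correlation). Glycolysis genes were lower in 12 and higher in 1 of 22 cases, or 13 and 1 adjusted over the list alone, with Pfkl 1.62-fold and Tpi1 1.53-fold lower (camera adjusted p = 7.7e-06, and adjusted p = 0.171 with an estimated correlation). Of 40 nuclear OXPHOS genes 12 were lower by either adjustment, among them Ndufv2 (152 ± 6.50 to 122 ± 14.2 CPM), against 7 without scaling (camera adjusted p = 0.000108, and adjusted p = 0.537 with an estimated correlation). The Th17 list had 8 genes higher and 1 lower of 23, or 9 and 2 adjusted over the list alone, with Pdpn, the podoplanin gene, 3.12-fold and the chemokine gene Ccl20 3.62-fold higher (camera adjusted p = 0.000159, and adjusted p = 0.171 with an estimated correlation). In the interferon-stimulated list 3 genes were higher and 6 lower, or 3 and 7 adjusted over the list alone, and Gbp2 was 2.55-fold lower (camera adjusted p = 0.206). Other lists called higher were Th1, Tfh, T cell activation, ATF4 and CD8 and cytotoxic. Those called lower were naive and memory T cells, the TCA cycle, cholesterol synthesis, NRF2 and glutathione, hypoxia, histone acetylation enzymes and p53. These other lists had a camera adjusted p between 0.000798 and 0.047, and between 0.171 and 0.621 with an estimated correlation.

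Il2 was 2.72-fold higher and, outside the lists, Il3, Ccn4 and Upp1 were higher by 6.42-, 5.43- and 5.00-fold. Myh11, Ckmt1, Socs2, a suppressor of cytokine signalling, Mov10 and Robo3 were lower by 15.5-, 3.52-, 2.77-, 2.72- and 2.64-fold. Il21, Il22 and Il23r did not pass the edgeR test. Without scaling 1911 genes were higher and 1254 lower. Pdhb (−0.16, adjusted p = 0.0278, libraries overlapping) lost its call without WT untreated 2, 3 or 4 or KO acetate 1 or 3 (−0.20 to −0.14). Dld (0.17, SE 0.067, adjusted p = 0.0701) passed without WT untreated 4 or KO acetate 4, with values between 0.10 and 0.21 over all single libraries left out.

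The interaction tested whether acetate acted differently in the 2 genotypes. In KO cells 8 of 21 interferon-stimulated and 6 of 26 ATF4 genes responded more negatively to acetate than in WT cells, and 7 of 22 glycolysis and 4 of 18 hypoxia genes more positively. The interferon list call held with an estimated correlation, and the other 3 were lost, at an adjusted p between 0.283 and 0.664. Fry called the interferon-stimulated and glycolysis lists (adjusted p = 2.48e-05 and 0.00206) but not the ATF4 and hypoxia lists (0.0657 and 0.0764). The acetate effect on Il23r was larger in KO cells by 1.56 (log2, SE 0.200, edgeR adjusted p = 0.000115). For Il17a the difference of 0.82 (SE 0.414, adjusted p = 0.234) and for Il17f that of 0.50 (SE 0.314, adjusted p = 0.341) did not pass the test. In all 1785 genes had an interaction, 955 positive and 830 negative.

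Of 21 interferon-stimulated genes 8 had a negative and none a positive interaction, or 15 adjusted over the list alone, 5 without scaling and 3 without the high-share libraries. The call held with an estimated correlation (camera adjusted p = 6.84e-08, and adjusted p = 0.0111 with an estimated correlation). Values were −0.61 for Irf1 (SE 0.110) and −2.27 for Isg15 (SE 0.433). Of 26 ATF4 genes 6 were negative, or 9 adjusted over the list alone, including Atf5 at −1.55 (SE 0.161) and Slc7a5 at −1.05 (SE 0.137) (camera adjusted p = 1.78e-07, and adjusted p = 0.552 with an estimated correlation). Of 15 serine and one-carbon genes 3 were negative, or 5 adjusted over the list alone, including Shmt2 at −0.75 (camera adjusted p = 0.00616, and adjusted p = 0.207 with an estimated correlation). Glycolysis genes were positive in 7 of 22 cases, or 10 adjusted over the list alone, with Slc16a3 at 1.61 (SE 0.184) and Hk1 at 0.65 (SE 0.096) (camera adjusted p = 1.75e-06, and adjusted p = 0.283 with an estimated correlation). Of 18 hypoxia genes 4 were positive by either adjustment, with Hif1a at 1.07 and P4ha1 at 0.32 (camera adjusted p = 0.0101, and adjusted p = 0.664 with an estimated correlation).

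Of 13 mitochondrially encoded genes 2 were negative by either adjustment, and 1 without the high-share libraries (camera adjusted p = 0.00616, and adjusted p = 0.664 with an estimated correlation). One of them, mt-Co1, at −0.52 (SE 0.112, edgeR adjusted p = 0.00598), had −0.46 with an adjusted p of 0.0583 without the 4 libraries with over 3% of counts on the unnamed gene, and reads of this gene are uncertain because of nuclear copies. The nuclear OXPHOS list had 3 negative and 1 positive of 40 by either adjustment, and 1 negative without the high-share libraries (camera adjusted p = 0.0235, and adjusted p = 0.812 with an estimated correlation). Outside the lists positive values included 2.75 for Ccn1, 2.14 for Slc17a6, 2.10 for the phosphatase gene Dusp3 and 2.02 for Fut4. Negative values included −3.31 for Fscn1, −2.92 for Kynu, −2.59 for Dagla and −1.97 for Plcd1. Without scaling 939 interactions were positive and 442 negative. Without the 4 libraries with over 3% of counts on the unnamed gene 1010 genes were called. The Pdhx interaction (0.34, adjusted p = 0.0443) ended when any single library other than WT acetate 3 or KO acetate 3 was left out (0.29 to 0.39).

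The study's comparison of knockout and acetate effects was followed gene by gene. Of the 5481 genes called between KO and WT untreated cells, 3622 (66.1%) were called in the opposite direction when acetate was added to KO cells, and 89 in the same direction. Atf5 and Shmt2 were among those that rose and then fell, and Slc16a3, Il23r and Ctla4 among those that fell and then rose. Independent calls would share 1198 genes in opposite directions. Both comparisons use the KO untreated libraries. In 5 simulations of unchanged groups neither comparison called any gene, so these simulations do not measure what the shared libraries add to opposite calls. With those libraries divided 2 and 2 between the comparisons, 2303 to 2438 genes were called in opposite directions and 35 to 156 in the same direction. The count was 2296 without replicate 3 of each group and 2342 without the 4 libraries with over 3% of counts on the unnamed gene.

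Across genes, which are not independent replicates, the log2 fold changes of these comparisons had r = −0.638 and rho = −0.652, with a covariance of −0.241. Simulated unchanged groups gave r = −0.508 (−0.538 to −0.471) and a covariance of −0.042, and the divided libraries r from −0.545 to −0.379 and covariances from −0.217 to −0.171. The KO effect without acetate and the WT acetate effect, which share the WT untreated libraries, had r = −0.05, rho = −0.089 and a covariance of −0.012. Simulations without effects gave r = 0.483 and a covariance of 0.038 for that pair, and divided libraries r from −0.223 to −0.143 with covariances from −0.066 to −0.038. Among calls, 331 genes changed the same way and 822 in opposite directions, against 423 and 424 for independent calls.

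The KO effects with and without acetate, which share no libraries, had r = 0.326 and rho = 0.379 across genes. Among calls, 105 genes changed in the same direction and 1 in the opposite one, against 27 of each for independent calls. Genes were then called in one pair of replicates and measured in the other. A line through the origin, of KO effects with acetate on those without, had a mean slope of 0.216 (0.255 over 2640 genes and 0.177 over 3187 genes). Such a slope gives genes with large changes most weight. Noise in the effects without acetate makes it smaller, so it is not the share of the knockout effect that remained. The acetate effects in WT and KO cells, which also share no libraries, had r = 0.565 and rho = 0.551, with 1816 genes called in the same direction and 30 in opposite directions, against 506 of each for independent calls.

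**Figure D3:**
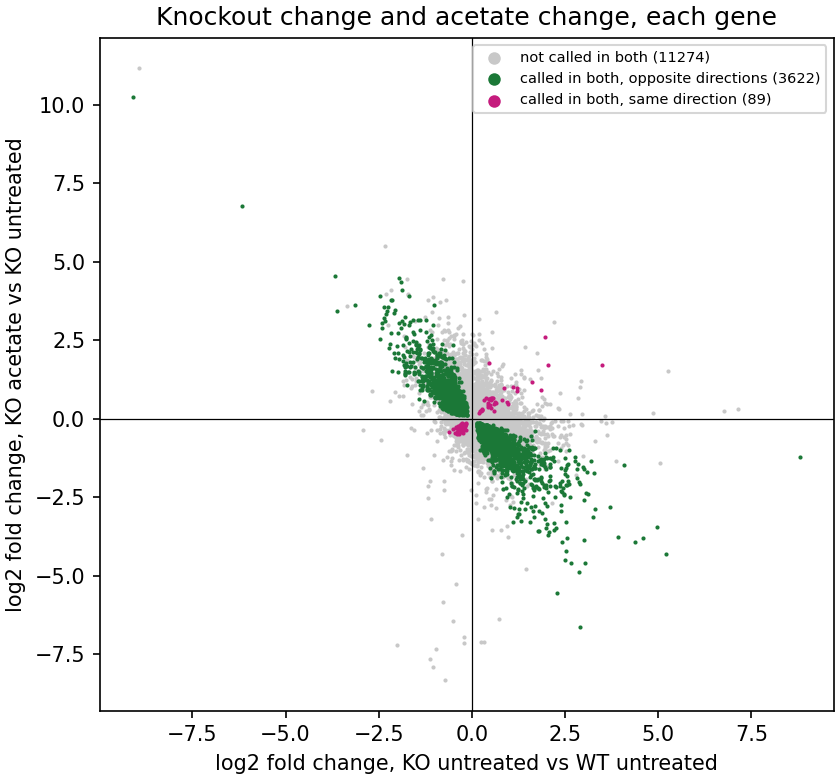
Log2 fold change of each of 14985 genes between KO and WT untreated cells (horizontal) and between KO acetate and KO untreated cells (vertical). Green points are the 3622 genes called in both comparisons in opposite directions, magenta points the 89 called in the same direction, and grey points the other 11274. KO untreated libraries enter both axes with opposite sign. Simulated unchanged groups gave r = −0.508 and a covariance of −0.042, against −0.638 and −0.241 here.

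**Figure D4:**
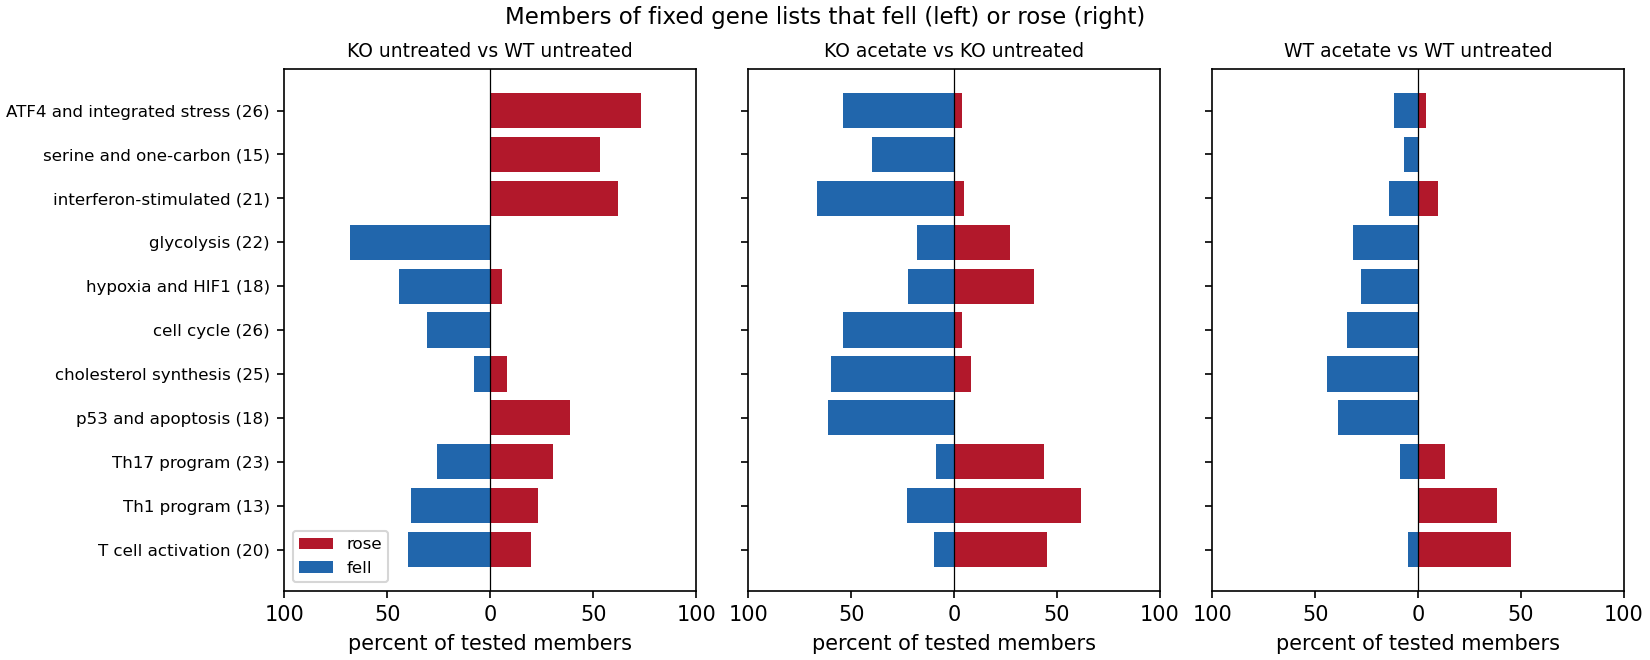
Percent of tested members (number in brackets) of 11 gene lists that fell, to the left of 0, or rose, to the right, in 3 comparisons. In KO against WT untreated cells 19 of 26 ATF4 genes and 13 of 21 interferon-stimulated genes rose and 15 of 22 glycolysis genes fell, and with acetate in KO cells 14 ATF4 and 14 interferon-stimulated genes fell. Without scaling the falls of cholesterol synthesis and cell cycle genes with acetate in KO cells numbered 6 and 4 in place of 15 and 14.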

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

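The tests of explanations given here, and the counts of other splits of the libraries, were all chosen after the results they bear on had been seen. The comparisons and the interaction test were planned.

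In 1785 genes the acetate effect differed between KO and WT cells by edgeR's interaction test, 50 of them among the 101 genes named in the text. The difference, KO minus WT on the log2 scale, was positive for 29. Among these were Ramp3 at 3.22, Ccn1 at 2.75, Slc17a6 at 2.14, Dusp3 at 2.10, Fut4 at 2.02, Tg at 1.97, Ccn4 at 1.93, Slc16a3 at 1.61, Vat1 at 1.55, Dclk1 at 1.39, Areg at 1.10 and Rcor2 at 0.95. Genes of T cell function included Il23r at 1.56, Ctla4 at 1.41, Stat4 at 1.39, Cxcr5 at 1.05, Gzmb at 0.96, Tnfrsf9 at 0.91, Nr4a1 at 0.90, Fasl at 0.87 and Stat3 at 0.58. Metabolic genes and those of the hypoxia response included Elovl6 at 1.10, Hif1a at 1.07, Bnip3 at 1.04, Hk1 at 0.65, Pfkfb3 at 0.60, Pdhx at 0.34, Tpi1 at 0.33 and P4ha1 at 0.32.

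The difference was negative for 21 named genes. Among these were Atf5 at −1.55, Slc7a5 at −1.05, Shmt2 at −0.75, Atf4 at −0.67, Phgdh at −0.56, Fasn at −0.50, Myc at −0.50, Sirt1 at −0.48 and mt-Co1 at −0.52. Interferon-stimulated genes were Isg15 at −2.27, Ifit1 at −2.24, Irf7 at −2.16, Gbp2 at −0.68 and Irf1 at −0.61. The others were Fscn1 at −3.31, Aqp4 at −2.95, Kynu at −2.92, Dagla at −2.59, Plcd1 at −1.97, Cd74 at −1.79 and Il2 at −0.62. Of 100 splits drawn with acetate labels exchanged within genotypes, 5 called as many genes as the 1785 observed, the real one included, and the highest other count was 4481. Those with 4481, 3014 and 1803 genes exchanged the acetate labels of all 8 KO libraries, and that with 2879 those of 2 WT untreated and 2 WT acetate libraries and of no KO library, so that the acetate effect in KO cells entered each of these whole. Such splits turn a real acetate effect into an interaction, so this count of splits does not settle whether chance can be excluded.

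One library stood far from the other 3 of its group in 33 of the 424 groups of 4 values examined, where chance gives about 1 in 20, or 21.2. WT untreated 1 held 7 of these, and KO acetate 2 and KO untreated 2 held 5 each. The unnamed gene took 5.89% of counts in WT untreated 1 (others 0.274% to 0.975%) and 8.0% in KO acetate 2 (others 0.753% to 1.53%). Lars2, annotated as a mitochondrial leucyl-tRNA synthetase gene, took 1.23% and 1.41% of counts in the same 2 libraries. It also took 1.46% in KO untreated 1 and 0.589% in KO untreated 2, and at most 0.205% outside the high-share libraries. Its share thus followed that of the unnamed gene, and the reason was not tested. Mitochondrial ribosomal RNA took 1.1% in KO untreated 1 (others 0.149% to 0.278%).

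Among named genes, WT untreated 1 stood apart for Ccnb1 (208 CPM), Cd8b1 (8.11), Ifng (0.447), Plcd1 (5.64) and Vat1 (27.0). The other WT untreated libraries that stood apart were replicate 2 for Ccl20 (10.2 CPM) and Sirt1 (31.9), replicate 3 for Tbx21 (28.1) and replicate 4 for Ifit1 (0.71) and Il21 (301). In KO untreated libraries, replicate 2 stood apart for Fscn1 (15 CPM), Gbp2 (232), Prrt1 (0.583), Sox4 (12.9) and Tnfrsf9 (70.5), and replicate 4 for Il23r (11.5) and Vat1 (12.4). In WT acetate libraries it was replicate 1 for Ccng1 (334 CPM) and Fscn1 (1.63), and replicate 3 for Bcl6 (32.7). In KO acetate libraries it was replicate 2 for Aldoa (906 CPM), Cd8b1 (15.9) and Il3 (28.7), replicate 3 for Myc (436) and Pfkfb3 (62.9), and replicate 4 for Ccnb1 (170), Hk1 (198) and Il23r (26.7).

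The wide difference between KO and WT cells without acetate, 5481 genes, involved 3 of the 4 libraries in which the unnamed gene took over 3% of counts. Without the 4 libraries the log2 fold changes of the called genes were a median of 0.953 times their earlier size (quartiles 0.819 and 1.09) and 100% kept their sign. These genes were selected in a fit that held all the libraries and then measured in some of the same libraries. Agreement was therefore likely from the start and decides little. The fit without the 4 libraries kept 3 WT and 2 KO untreated libraries and called only 3361 genes, 3185 of them among the 5481. Calls made without those libraries argue against them as the whole cause. Only the real split of the 35 possible splits of these 8 libraries gave 5481 calls (1 of 35, highest other 3). This argues against a chance arrangement of these libraries. It cannot exclude a chance difference between animals or cultures, since the labels do not say which libraries came from separate ones. Loss of PDH may account for the difference, as a hypothesis, since any other difference between the animals or cultures of the 2 genotypes was not tested.

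Interferon-stimulated genes were higher in KO cells without acetate, in 13 of 21 cases, and fell with acetate, in 14 of 21. Without the 4 libraries with over 3% of counts on the unnamed gene the list's median log2 fold change was 0.48, against 0.523 with them, which argues against those libraries as the source. Myeloid or dendritic cells left after the sort of naive CD4 T cells could bring such transcripts, yet the summed CPM of the 6 tested markers of the 17 fixed rose from 5.25 to 5.3, or 0.0195% of the 238 CPM rise of the list, with Lyz2 below 1 CPM in both groups. Flt3, at 0.115 and 0.524 CPM, was called higher (edgeR adjusted p = 0.0421), which keeps such cells open as a source. A response to the loss of PDH within the T cells stays open and was not tested.

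Most genes called for the knockout were called the opposite way for acetate in KO cells, 3622 of 5481. The KO untreated libraries enter both comparisons, but with those libraries divided 2 and 2 the opposite calls were at least 15.1 times those in the same direction in each of 6 divisions, which argues against the shared libraries as the whole cause. No other split of the 8 KO libraries called as many genes for acetate as the real one (1 of 35 splits, highest other 1). That argues against a chance arrangement of these libraries, but cannot exclude a chance difference between animals or cultures. Whether acetate stands in for a product of PDH was not tested. Of these 3622 genes, 817 were also called for acetate in WT cells in the same direction as in KO cells and 30 in the other, so an effect of acetate that does not depend on PDH stays open for part of them.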

How the results depend on the processing

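Chosen after seeing the data were the fits without the 4 libraries with over 3% of counts on the unnamed gene, with that gene's share as a covariate, and with a term for replicates 1 and 2 against 3 and 4, and the counts of other splits. No named gene or list that was called, in the reported fit or under another setting it was run with, reversed its direction, and no gene shared between calls of the reported edgeR fit and calls under another setting changed direction. Without scaling the balance of calls for KO acetate against WT untreated turned from 1935 higher and 2019 lower to 1911 and 1254. The medians of some lists that did not pass also changed sign, such as that of the MYC list for acetate in KO cells (−0.05 to 0.05) and of the cell cycle list for the interaction (−0.02 to 0.03). Of the single-gene values under all alternatives 3733 kept their side of the threshold, 92 lost and 26 gained it, and of the list values 617 kept, 81 lost and 22 gained it.

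The count of genes between KO acetate and WT acetate cells depended most on the setting. It was 150 as reported, 78 without scaling, 826 in DESeq2, 16 in a fit of only these groups, 535 without the high-share libraries, 74 with the share as a covariate and 234 with the term for replicates 1 and 2 against 3 and 4. It ranged from 21 to 661 when a single library was left out. Of the 35 splits of these 8 libraries 2 gave 150 genes or more, the real one included. The other gave 188 and set replicates 1 and 2 against 3 and 4 of both genotypes. This count of splits, made without a replicate term, does not exclude chance. With the replicate number as a block the real split called 408 genes, and no splits were counted in that fit. Without the high-share libraries the count between KO and WT untreated cells was 3361, that of interactions 1010 and that of opposite calls for knockout and acetate 2342. In the other comparisons the real split was the only one of 35 to give as many genes, with the highest other at 2 for WT acetate against WT untreated and 0 for KO acetate against WT untreated. Of 100 interaction splits 5 gave as many.

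With a single library left out, the counts ranged from 4491 to 5454 for KO against WT untreated, 5817 to 6460 for acetate in KO cells, 1569 to 2370 for acetate in WT cells, 2944 to 3896 for KO acetate against WT untreated and 1277 to 1999 for the interaction. With a replicate number left out of every group, opposite calls ranged from 2296 to 3097 and the correlation of KO effects with and without acetate from 0.263 to 0.336.

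Camera with an estimated correlation called 0 lists in KO against WT untreated, 0 in KO acetate against WT acetate, 0 in WT acetate against WT untreated, 1 in KO acetate against KO untreated, 0 in KO acetate against WT untreated and 1 for the interaction, where the preset correlation called 6, 12, 11, 10, 16 and 7. Fry called 11, 0, 12, 19, 15 and 5. The camera test with an estimated correlation uses both that correlation and fewer degrees of freedom, and these were not separated. For the other changes the cause was not tested, except that leaving libraries out lowers the number of samples.

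The replicate numbers were not treated as pairing the samples, since the labels do not tie them and in no pair of groups did every same-number pair correlate over 0.1. Of 24 pairs of groups and numbers, 9 correlated over 0.1 (−0.084 to 0.229, mean 0.064). For different numbers the mean was −0.021. Group means were subtracted first, so that value follows largely from the mean for same numbers and is no separate comparison. Of 16 libraries 9 correlated best with their own number, a hint that some numbers share a structure. The bound of 0.1 is not a test of pairing, so these values do not exclude it. For KO untreated with KO acetate the correlations were 0.086 to 0.165. With the replicate number as a block the counts were 5886, 408, 2632, 6851, 4401 and 2259 in the same order, and opposite calls 3924. Il21 passed between KO and WT cells with acetate under the block (log2 fold change 0.40, adjusted p = 0.036), and Il17a did not (0.85, adjusted p = 0.1). The correlations and the slope were not run with the block, nor the slope with a replicate left out. The pseudocounts and filters planned in case the table did not hold counts were not run, since it did. DESeq2 gave no adjusted p to 3325 genes between KO and WT with acetate and to 2119 for the interaction. At 24.57 to 33.72 M counts, 1.5-fold interactions were recovered in 49.3% of simulated cases, all of them genes with a mean count of at least 50. Smaller interactions can be missed, and recovery at lower counts was not measured.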

Other observations

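The list tests in this part were planned. Between KO and WT cells without acetate, regulators of other T cell fates moved both ways. The Treg list had 2 genes higher and 6 lower of 13 by either adjustment (camera adjusted p = 0.124, fry adjusted p = 4.95e-05). The T cell activation list had 4 higher and 8 lower of 20 (camera adjusted p = 0.24), the Th1 list 3 and 5 of 13 (0.573), the Th2 list 1 and 3 of 7 (0.573), the Tfh list 2 and 3 of 8 (1) and the naive and memory list 1 and 1 of 12 (0.499). MYC and ribosome biogenesis genes rose in 8 of 20 cases with none lower, or 5 and 1 without scaling (camera adjusted p = 0.082, and 0.00225 without the high-share libraries, a fit chosen after seeing the data), led by Myc. Of 18 p53 and apoptosis genes 7 rose and none fell, or 6 and 1 without scaling, and 4 rose without the high-share libraries (camera adjusted p = 0.0976).

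In KO cells without acetate Fasn rose from 484 ± 50.5 to 876 ± 93.9 CPM and the elongase gene Elovl6 fell from 72.8 ± 4.71 to 32.8 ± 4.07 CPM (edgeR adjusted p = 3.13e-06 and 2.82e-08, 4 libraries per group without overlap). The fatty acid synthesis list had 6 genes higher and 2 lower of 15 (camera adjusted p = 0.449). The remaining lists, by the preset camera test between KO and WT untreated cells, did not pass. Higher and lower were 2 and 2 of 25 for cholesterol synthesis (adjusted p = 0.573), 3 and 7 of 19 for fatty acid oxidation (0.336), 3 and 8 of 24 for the TCA cycle (0.124), 0 and 3 of 10 for acetate and acetyl-CoA (0.56), and 2 and 4 of 13 for the PDH complex and regulators (0.813). They were 3 and 9 of 40 for nuclear OXPHOS (0.499), 2 and 0 of 13 for mitochondrially encoded genes (0.336), 4 and 5 of 15 for glutamine and aspartate (0.573), 3 and 5 of 18 for NRF2 and glutathione (0.813) and 2 and 5 of 25 for histone acetylation enzymes (0.573). For nuclear OXPHOS the counts were 0 and 11 without scaling, and 0 and 5 without the high-share libraries.

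Of the tested B cell, myeloid and dendritic markers, all but Cd74 had group means of at most 8.67 CPM. The CD8 marker Cd8b1 reached 15.95 CPM in WT acetate 2. Cd74, the invariant chain gene of MHC class II, was at 62.7 ± 6.03 CPM in WT untreated, 202 ± 16.7 CPM in KO untreated, 57.8 ± 5.65 CPM in WT acetate and 53.9 ± 11.6 CPM in KO acetate libraries (edgeR adjusted p = 6.98e-08 for KO against WT untreated). The B cell gene Cd79a was at 0.445 and 0.574 CPM in the untreated groups. H2-Ab1, an MHC class II gene, was at 4.60 ± 1.42 and 2.92 ± 0.836 CPM there and at 8.67 ± 1.5 CPM in KO acetate cells. The untreated difference was −0.65 (adjusted p = 0.0412, libraries overlapping) and its call ended without WT untreated 2, 3 or 4 or KO untreated 1, 3 or 4 (−0.84 to −0.50). Of 10 B cell genes 1 rose and 1 fell in KO untreated cells (camera adjusted p = 0.187). Of 6 CD8 and cytotoxic genes 1 rose and 3 fell (0.336), Cd8b1 from 9.09 ± 0.655 to 6.20 ± 1.23 CPM. Of 6 myeloid and dendritic genes 1 rose (0.813) and of 5 gamma delta T and ILC genes 1 rose (0.344). No erythroid or platelet gene was among those tested. Xist at 559 to 1090 CPM and the Y-linked Kdm5d at 2.48 to 7.51 CPM were found in every library. The other Y-linked genes of that list, Ddx3y, Eif2s3y and Uty, were not among those tested. Kdm5d alone therefore does not show that male cells were present. Xist and Kdm5d were both called higher in KO than in WT untreated cells, and lower with acetate in KO cells.

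Ifng stood at 0.656 ± 0.140, 2.00 ± 0.760, 3.04 ± 0.972 and 4.54 ± 1.52 CPM in WT untreated, KO untreated, WT acetate and KO acetate libraries, and its level outside the WT comparison was chosen for mention after its values were seen. Mitochondrial transcripts made up 3.75 ± 0.0934%, 4.66 ± 0.626%, 4.11 ± 0.338% and 3.73 ± 0.434% of counts in the same order (SD, n = 4).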
